A study of Mus musculus with 4 samples.

How the data were processed

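Gene expression was measured by RNA sequencing of total RNA from 4 cultures of mouse liver cells. RNA was extracted with a Qiagen RNeasy kit and libraries were built by Novogene, per the labels' protocols. The authors deposited a table of TPM, named as such in the table, for 24493 gene symbols in the 4 libraries. The submitters' processing notes name Salmon, DESeq2 and the mm10 genome build without versions, and they give no role for DESeq2. The transcript annotation is not named in the labels. TPM (length-corrected shares of each library) divides each gene's estimated reads by its transcript length and scales every library to the same total. It therefore keeps no sequencing depth, so the depth of each library and the counting error behind each value were unknown, and a gene that takes a larger share lowers the TPM of all others. Whole reads cannot be recovered from TPM, so no count model was fitted.

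Groups were taken from the sample titles: Bil_2D (hepatocyte-derived biliary cells in 2D culture) and Hep_3D (hepatocytes in 3D culture), with 2 libraries each. Replicate 1 of both groups carried the clone number 15C7 and replicate 2 carried 19H5. The labels say that the samples come from separate clones and nothing more on their independence, such as donor animals or separate experiments, so p-values measure the spread between these samples, which may be partly technical. The pairing of libraries by clone comes from the clone numbers in the labels, and across genes the deviations of same-clone libraries from their group means correlated at 0.414.

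Genes with at least 1 TPM in at least 2 of the 4 libraries were tested (12336), on log2(TPM + 1), with limma (lmFit, then eBayes with a trend) for Hep_3D against Bil_2D without other terms, which left 2 residual degrees of freedom and a prior of 2.29. P-values were adjusted over all genes tested by the Benjamini-Hochberg method and called under 0.05. The clones were compared in the same way with cell state as a term, which left 1 residual degree of freedom. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. Genes listed at 0 in a library are given by library, because an exact 0 in a table without counts can be a failed estimate.

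Because the share of TPM held by the most abundant genes differed between groups, results are given on a second scale, TPM divided by median-of-ratios size factors over genes with at least 1 TPM in every library. Median-of-ratios scaling was one of the fixed alternatives, and printing it beside many of the results was decided after seeing the data. The size factors set the groups apart by 0.82 log2 units, and the median difference between a gene's fold changes on the 2 scales was 0.76. Other alternatives were pseudocounts of 0.1 and 5, no filter or a filter of 5 TPM, quantile normalization, leaving out the 50 most abundant genes and rescaling the rest, eBayes without a trend or with the robust option, clone as a replicate block, a minimum absolute log2 fold change of 1, leaving out each library in turn, and for the clones a fit without cell state. These designs, alternatives, gene lists and the rule for named genes were fixed before the data were examined. The runs of the median-of-ratios scale with the replicate block, with a minimum fold change or with libraries left out were chosen after seeing the data, as were the counts on that scale of non-overlapping groups and of shared direction in the clones. With a library left out, the filter and scaling of all 4 libraries were kept, and the group's lone sample was taken to vary like the other group.

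The 31 gene lists covered hepatocyte functions (secreted plasma proteins, transcription factors, cytochrome P450, conjugation, bile acids, urea cycle and amino acids, glucose production), biliary markers, glycolysis, lipid metabolism (fatty acid oxidation, cholesterol synthesis, fatty acid and triglyceride synthesis), signalling and structure (YAP/TAZ, Notch, mesenchymal and TGF-beta, basement membrane, junctions and keratins), cell cycle, fetal liver, stress (immediate early and unfolded protein response, p53, interferon, chemokines and acute phase, hypoxia), lobule zones (pericentral, periportal), markers of other cell types (fibroblast and stellate, endothelial, macrophage and leukocyte, red blood cell) and mitochondrially encoded genes, of which 0 matched the table and 0 were tested. Some genes stand in more than one list, so lists are not independent. Lists with at least 5 genes tested (26) were compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01 and adjusted together. Of these lists 18 passed, 13 upward and 5 downward, and 18 with the replicate block, while 0 passed with a correlation estimated from the residuals. With an estimated correlation camera tests on the 2 residual degrees of freedom and has little power. A failure there does not show that correlation between genes accounts for a list. The urea cycle and amino acid list had an estimated correlation of -0.0143, below the preset value, and its camera adjusted p still went from 5.43e-29 to 0.151. Counts were also adjusted over each list alone, and 11 of 30 lists then gave other counts.

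Named genes were up to 10 per direction with the largest absolute log2 fold change among genes that passed, had a mean of at least 10 TPM in the higher group and did not overlap between groups, passing over symbols that are a Gm number or end in Rik. From each list, up to 2 rising and 2 falling members that passed with the largest change were added, or the 1 or 2 most abundant members where none passed. Alb, Hnf4a, Cyp7a1, Afp, Krt7, Krt19, Sox9, Epcam and Spp1 were always reported. Some genes that the rule names are not reported here. For the clones, at most 5 per direction were named, ranked by moderated t where fewer than 10 passed. A gene named outside this rule is said to be so. Coordinates are those of the GENCODE M21 annotation of GRCm38, the assembly called mm10, and are whole gene spans on which 12150 of the genes tested matched by a unique symbol.

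The tests were run on simulated data for Hep_3D against Bil_2D: over 12336 simulated genes, with 200 changed, limma recovered 23.9% of changes of log2 size 1, 92.5% of size 2 and 100% of size 4, with 9 false calls among 12136 unchanged genes. With standard deviations drawn from the fitted prior it recovered 2.99%, 58.2% and 97%, with 9 false calls. In both runs the changed genes were drawn from those above a minimum mean level, and noise was independent with no clone effect. In the data 7241 genes were called and same-clone deviations correlated at 0.414, so these rates may not carry over. Camera gave a moved list of 30 genes an adjusted p of 8.14e-48 and called 0 of 20 unmoved lists. Noise was independent between genes there too, so this check cannot tell whether camera's preset correlation suits the real lists. In the data the estimated correlation of the lists ran from -0.0467 (Notch pathway) to 0.91 (cell cycle). Raising 50 genes alone, picked at random above a minimum mean level, moved the simulated median log2 change to -0.22 on the TPM scale and 0.000373 on the median-of-ratios scale. These were not the most abundant genes, so -0.22 is no measure of the shift expected in the data. Analyses used R 4.3.3, limma 3.58.1, Python 3.11.15, matplotlib 3.10.9 and numpy 2.4.6.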

Results

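RNA sequencing compared cultured mouse hepatocytes with biliary cells derived from hepatocytes. The 4 libraries came from 2 clones of C57BL/6 hepatocyte origin, 15C7 and 19H5, and each clone gave a library in each state. The Bil_2D group held the hepatocyte-derived biliary cells, grown in 2D culture (n = 2), and the Hep_3D group held hepatocytes in 3D culture (n = 2). Replicate 1 of each group was clone 15C7 and replicate 2 was clone 19H5. Culture format went with cell state in every library, so each difference below is a difference in both. The values were TPM, the length-corrected share of each transcript, for 24493 gene symbols. They summed to 1000000 in each library, so the sequencing depth was unknown. Genes with at least 1 TPM numbered 12266 and 11907 in Bil_2D replicates 1 and 2, and 11747 and 11247 in Hep_3D replicates 1 and 2. Across genes, which are not independent replicates, Pearson's r of log2 values was 0.962 between the Bil_2D libraries, 0.955 between the Hep_3D libraries and 0.757 to 0.799 between libraries of different groups.

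The first comparison asked which transcripts differed between the hepatocyte and biliary cultures. Hepatocyte cultures held higher levels of secreted plasma protein, cytochrome P450, urea cycle and gluconeogenic transcripts, and biliary cultures held higher levels of keratin 19, YAP target, basement membrane and cell cycle transcripts. None of these gene lists passed camera with an estimated correlation (adjusted p from 0.151 to 0.623), a test with little power at 2 residual degrees of freedom. Single libraries also mattered: 29 cell cycle genes fell, but 9 without Bil_2D replicate 1 and 7 without Bil_2D replicate 2. The number of glucose production genes that rose went from 11 to 5 without either Bil_2D replicate, and to 7 without Hep_3D replicate 2. Of 12336 genes tested with limma at n = 2 per group, 7241 (58.7%) differed at an adjusted p under 0.05, with 839 higher and 6402 lower in Hep_3D. The 50 most abundant genes took 42.8% and 46.2% of all TPM in Hep_3D replicates 1 and 2, against 17.9% and 19.5% in Bil_2D. The entry Mir6236, named outside the rule for named genes, took 6.39% and 3.91% in Hep_3D replicates 1 and 2, against 1.31% and 2.41% in Bil_2D. The median log2 fold change of all genes was -0.73 on the TPM scale and -0.02 after median-of-ratios scaling. On the median-of-ratios scale 2642 genes differed, 1465 higher and 1177 lower. Calls in the same direction on both scales numbered 825 higher and 1177 lower, and 0 genes were called in opposite directions. The share of called genes that were higher was 11.6% on the TPM scale and 55.5% on the median-of-ratios scale.

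**Figure D1:**
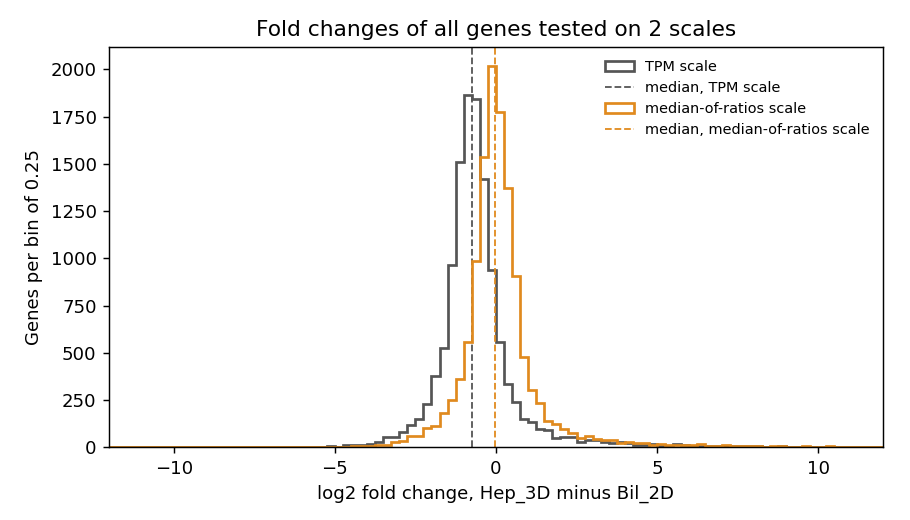
Histogram of log2 fold changes (Hep_3D minus Bil_2D, bins of 0.25) of the 12336 genes tested, with the number of genes per bin on the vertical axis, for the TPM scale (grey) and the median-of-ratios scale (orange). Dashed lines mark the medians, -0.73 and -0.02.

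Leaving out a library lowered both counts: the TPM scale gave 2738 genes without Bil_2D replicate 1, 2627 without Bil_2D replicate 2, 4537 without Hep_3D replicate 1 and 4134 without Hep_3D replicate 2. The median-of-ratios scale gave 340, 188, 818 and 613 in the same order. The groups did not overlap for 10240 genes (83%) on the TPM scale, which holds the shared shift, and for 8431 (68.3%) on the median-of-ratios scale, where chance gives 33.3%. An exact two-sided permutation test of 2 against 2 libraries cannot go below p = 0.333. Below, log2 fold changes are Hep_3D minus Bil_2D on the log2(TPM + 1) scale, which understates changes of low genes. The value relative to the median shift is given as that on the median-of-ratios scale. Rose and fell refer to limma's test on the TPM scale unless the other scale is named.

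Among the genes with the largest rises were secreted proteins. Serpina3n, a serine protease inhibitor (chromosome 12, 104406729 to 104414329), rose from 0.365 ± 0.232 to 3071 ± 2102 TPM (SD, n = 2; log2 fold change 10.95, SE 0.55, adjusted p = 0.00306 in limma). Ahsg, which encodes the plasma protein fetuin-A (chromosome 16, 22891277 to 22899449), rose from 9.16 ± 0.222 to 8196 ± 1366 TPM (SD, n = 2; log2 fold change 9.65, SE 0.16, adjusted p = 0.000874). Saa2, an acute phase serum amyloid, rose from 10.6 ± 5.53 to 11431 ± 4320 TPM, and Fgg, the fibrinogen gamma chain, from 19.4 ± 7.04 to 14252 ± 2554 TPM (SD, n = 2). Vtn (vitronectin), Cfhr2 and the imprinted growth factor gene Igf2 (chromosome 7, 142650766 to 142666816) had log2 fold changes of 9.55, 9.40 and 9.76. Serpina3k, Wfdc21 and Spink1 also passed, and each was listed at 0 in a Bil_2D library. Serpina3k had 0.579 and 0 TPM in Bil_2D replicates 1 and 2 and 4496 and 560 in Hep_3D. Wfdc21 had 0.462 and 0 against 1659 and 1238. Spink1 had 0 and 1.74 against 1957 and 1253. Serpina3k, Serpina3n and Saa2 have close paralogs, so their separate values are uncertain.

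The largest fall was that of Sprr1a, a cornified envelope protein of squamous epithelium (chromosome 3, 92483952 to 92485895), from 10319 ± 1398 to 2.77 ± 0.0381 TPM (SD, n = 2; log2 fold change -11.41, SE 0.15, adjusted p = 0.000406 in limma; -10.69 on the median-of-ratios scale). Krt19, the keratin of bile duct epithelium (chromosome 11, 100140810 to 100148665), fell from 1183 ± 610 to 8.51 ± 10.5 TPM (log2 fold change -7.53, SE 1.10, adjusted p = 0.00873), and its adjusted p was 0.0546 without Bil_2D replicate 2. Msln (mesothelin), Fscn1 (the actin bundling protein fascin), Stra6, Cyr61 (a matricellular YAP target), Ckb (brain creatine kinase) and Dio3 (a thyroid hormone deiodinase) fell with log2 fold changes of -6.34, -5.72, -5.38, -5.17, -5.16 and -5.12. Id3, an inhibitor of basic helix-loop-helix factors, fell from 463 ± 241 to 9.24 ± 10.5 TPM (SD, n = 2), with an adjusted p of 0.0111. This was 0.0637 without Bil_2D replicate 1 and 0.0522 without Bil_2D replicate 2. Hmga1b, a near-identical copy of Hmga1 and so uncertain, had 58.9 and 61.9 TPM in Bil_2D and was listed at 0 in both Hep_3D libraries. On the median-of-ratios scale each of these genes also passed.

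**Figure D2:**
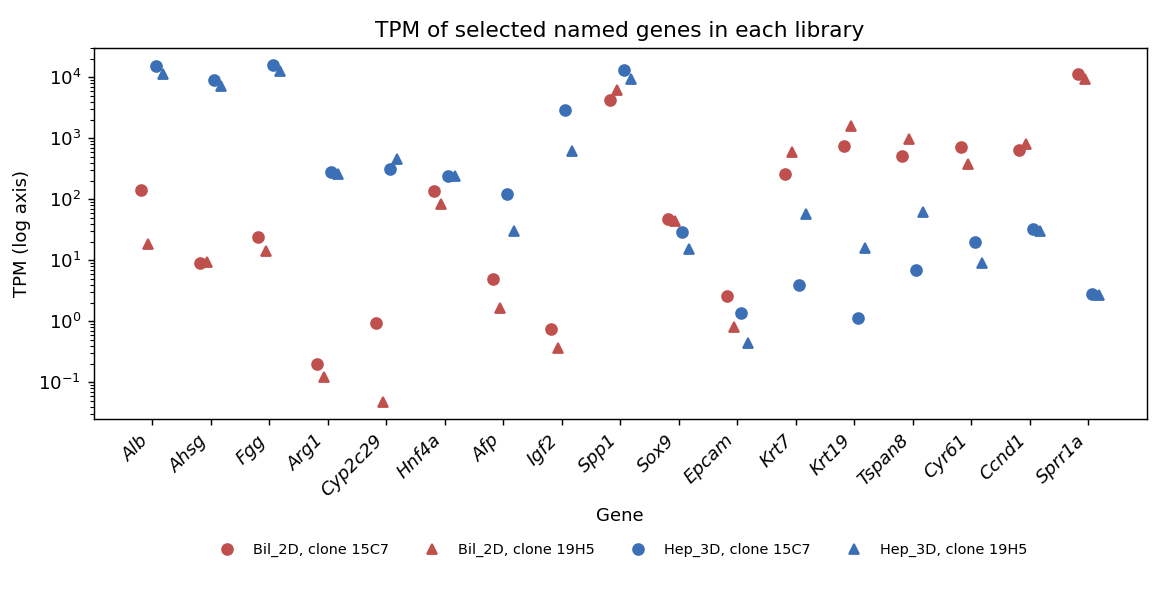
TPM (log axis) of selected named genes in each of the 4 libraries, with colour for the group and circles or triangles for clones 15C7 and 19H5. Alb lies at 140 and 18.4 TPM in Bil_2D replicates 1 and 2 and at 15033 and 11216 TPM in Hep_3D, and Sprr1a is highest in Bil_2D.

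Transcripts of plasma proteins secreted by hepatocytes rose together: 27 of 30 were higher and 0 lower, 29 and 0 adjusted over the list alone, and 26 and 0 on the median-of-ratios scale. Their summed share of TPM was 24.4% and 21.2% in Hep_3D replicates 1 and 2, against 1.16% and 0.833% in Bil_2D. The camera test gave an adjusted p of 1.03e-43 with a preset correlation of 0.01 between genes, and the adjusted p was 0.151 with an estimated correlation. Alb, which encodes albumin (chromosome 5, 90460897 to 90476602), rose from 79.2 ± 86 to 13125 ± 2699 TPM (SD, n = 2; log2 fold change 7.96, SE 0.996, adjusted p = 0.00718 in limma). Ttr (transthyretin), Serpina1a and Serpina1b were the members that did not pass, with adjusted p of 0.055, 0.0662 and 0.0986, and they were named after their values were seen.

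Genes of drug metabolism and bile acid handling were mostly higher. Of 21 cytochrome P450 list members tested, 18 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 1.24e-24; adjusted p = 0.151 with an estimated correlation). Cyp2c29 rose from 0.499 ± 0.638 to 385 ± 107 TPM and Cyp2d10 from 0.799 ± 0.905 to 323 ± 55 TPM (SD, n = 2), both from families of close paralogs and so uncertain. Por, the reductase that supplies electrons to these enzymes, fell with a log2 fold change of -1.18 that was -0.37 on the median-of-ratios scale (adjusted p = 0.134 there). Of 24 conjugation enzymes, 13 rose and 2 fell, the same adjusted over the list alone, and 4 rose and 1 fell without Bil_2D replicate 2 and 5 rose without Hep_3D replicate 2 (camera adjusted p = 9.8e-14; adjusted p = 0.243 with an estimated correlation). Gstm3 and Sult1d1 rose (log2 fold changes 5.58 and 5.29) while the glutathione transferases Gsta1 and Gsta4 fell (-3.70 and -3.03). The adjusted p of Gsta1 was 0.0571 without Bil_2D replicate 1 and 0.0627 without Bil_2D replicate 2. Of 21 bile acid synthesis and transport genes, 12 rose and 1 fell, or 15 and 4 adjusted over the list alone (camera adjusted p = 1.79e-14; adjusted p = 0.215 with an estimated correlation). The number that fell was 2 without Hep_3D replicate 2 and 3 with the replicate block. Slc27a5 and Baat, which act in bile acid conjugation, rose to 180 ± 32.3 and 27.8 ± 0.266 TPM (SD, n = 2), and the efflux transporter Abcc4 fell from 187 ± 56.6 to 20.1 ± 2.76 TPM. Cyp7a1, the rate-limiting enzyme of classical bile acid synthesis, was under the filter, with 0.0411 and 0.0565 TPM in Bil_2D and 0.169 and 0.371 in Hep_3D.

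Of 19 hepatocyte transcription factors tested, 10 rose and 2 fell, the same adjusted over the list alone. The number that rose was 6 without Hep_3D replicate 1 and 6 without Hep_3D replicate 2, and the number that fell was 1 without Bil_2D replicate 1 and 1 without Bil_2D replicate 2 (camera adjusted p = 1.07e-10; adjusted p = 0.229 with an estimated correlation). Creb3l3 rose from 1.91 ± 1.46 to 77.9 ± 15.7 TPM and Cebpa, a regulator of hepatocyte metabolic genes, from 4.78 ± 0.184 to 91.8 ± 20.4 TPM (SD, n = 2). Hnf4a, the nuclear receptor central to hepatocyte identity, was already at 111 ± 37.5 TPM in Bil_2D and rose to 241 ± 4.63 TPM (SD, n = 2; log2 fold change 1.15, adjusted p = 0.0233 in limma, 1.96 on the median-of-ratios scale). Its adjusted p was 0.0523 without Bil_2D replicate 2, 0.0973 without Hep_3D replicate 1 and 0.0969 without Hep_3D replicate 2. Foxa2 and Esrra fell with log2 fold changes of -1.52 and -0.97 on the TPM scale, and neither passed on the median-of-ratios scale (-0.72 and -0.17, adjusted p = 0.0756 and 0.6). Without Bil_2D replicates 1 and 2 in turn the adjusted p of Esrra was 0.0819 and 0.0762.

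Biliary epithelial markers went both ways: 2 of 22 rose and 11 fell, 4 and 13 adjusted over the list alone, and 3 and 6 on the median-of-ratios scale. Without Bil_2D replicate 2, 6 fell. The number that rose was 1 without Bil_2D replicate 1, 1 without Bil_2D replicate 2, 3 without Hep_3D replicate 1 and 0 without Hep_3D replicate 2, and 4 with the replicate block. The median log2 fold change was -1.43 while the camera test leaned upward against other genes, without passing (adjusted p = 0.539), and leaned downward on the median-of-ratios scale (adjusted p = 0.173). Krt7 fell from 424 ± 234 to 30.1 ± 37.1 TPM (SD, n = 2; log2 fold change -4.55, adjusted p = 0.0392 in limma). On the median-of-ratios scale its log2 fold change was -3.77 and did not pass (adjusted p = 0.117 in limma). The fold change was -5.14 without Bil_2D replicate 1, -3.95 without Bil_2D replicate 2 and -2.77 without Hep_3D replicate 1, and the call was lost in each. Tspan8 fell from 736 ± 327 to 34.5 ± 38.9 TPM (adjusted p = 0.0202). Its adjusted p was 0.0667 on the median-of-ratios scale, 0.0731 without Bil_2D replicate 1 and 0.0947 without Bil_2D replicate 2. Sox9 stood at 45.5 ± 2.96 TPM in Bil_2D and 22.2 ± 9.86 in Hep_3D and missed the threshold (adjusted p = 0.0503). It passed with clone as a replicate block (adjusted p = 0.0302), without Hep_3D replicate 1 (0.0302), with log2(TPM + 5) (0.0464) and with a filter of at least 5 TPM in at least 2 libraries (0.0425). On the median-of-ratios scale its adjusted p was 0.565. Epcam was low in both groups, at 1.7 ± 1.26 and 0.895 ± 0.644 TPM (SD, n = 2; adjusted p = 0.416 in limma). Spp1 (osteopontin) rose from 5134 ± 1355 to 11188 ± 2694 TPM (log2 fold change 1.13, adjusted p = 0.0359). It lost its call at 0.0611 with the replicate block and at 0.0648 to 0.152 as each of the 4 libraries was left out in turn. Its log2 fold change was 1.95 on the median-of-ratios scale (adjusted p = 0.0283) and 0.02 after quantile normalization (0.972), and without the filter its adjusted p was 0.177. Ggt1, a gamma-glutamyl transferase, rose from 2.74 ± 1.31 to 13.2 ± 0.297 TPM, with adjusted p of 0.0518 and 0.0529 without Hep_3D replicates 1 and 2.

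Amino acid and glucose metabolism genes of hepatocytes were higher. Of 24 urea cycle and amino acid breakdown genes, 20 rose and 1 fell, or 21 and 1 adjusted over the list alone (camera adjusted p = 5.43e-29; adjusted p = 0.151 with an estimated correlation). Arg1, the arginase of the urea cycle, rose from 0.16 ± 0.0552 to 269 ± 15.4 TPM, and Hpd, of tyrosine breakdown, from 0.264 ± 0.173 to 235 ± 30.8 TPM (SD, n = 2). Oat, ornithine aminotransferase, fell by 0.90 on the log2 scale but stood at -0.09 on the median-of-ratios scale (adjusted p = 0.654). Its TPM-scale adjusted p was 0.051 and 0.0552 without Bil_2D replicates 1 and 2. Of 14 glucose production and glycogen genes, 11 rose and 0 fell, the same adjusted over the list alone. The number that rose was 5 without Bil_2D replicate 1, 5 without Bil_2D replicate 2 and 7 without Hep_3D replicate 2 (camera adjusted p = 1.95e-14; adjusted p = 0.177 with an estimated correlation). G6pc, which releases free glucose, had 0.362 and 0 TPM in Bil_2D and 34.5 and 25.3 in Hep_3D. Of 17 glycolysis genes, 0 rose and 13 fell, the same adjusted over the list alone, and 4 fell on the median-of-ratios scale. The camera adjusted p was 0.0235, 0.065 without Hep_3D replicate 1, and adjusted p = 0.569 with an estimated correlation. The number that fell was 7 without Bil_2D replicate 2, 8 without Hep_3D replicate 1 and 7 without Hep_3D replicate 2. Pkm, the pyruvate kinase of proliferating tissues, fell from 2776 ± 173 to 331 ± 26.5 TPM and Aldoa from 1428 ± 405 to 246 ± 85.6 TPM (SD, n = 2), and both also passed on the median-of-ratios scale.

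Lipid genes formed 3 lists. In fatty acid oxidation and ketogenesis, 6 of 20 rose and 6 fell, the same adjusted over the list alone, against 12 and 0 on the median-of-ratios scale (camera adjusted p = 0.000108; adjusted p = 0.242 with an estimated correlation). With single libraries left out, 2 to 4 rose and 0 or 1 fell: 3 and 1 without Bil_2D replicate 1, 2 and 1 without Bil_2D replicate 2, 4 and 0 without Hep_3D replicate 1, and 3 and 1 without Hep_3D replicate 2. Acaa2 rose from 73.4 ± 0.043 to 306 ± 18.7 TPM (SD, n = 2). Cpt1a fell by 0.76 on the TPM scale and stood at 0.05 on the median-of-ratios scale (adjusted p = 0.856 there). On the TPM scale its adjusted p was 0.0513 to 0.0732 as each of the 4 libraries was left out. Acaa1b fell by 1.92, with an adjusted p of 0.0916 on the median-of-ratios scale and 0.0594 without Hep_3D replicate 1. Of 20 cholesterol synthesis genes, 7 rose and 1 fell, or 5 and 1 adjusted over the list alone (camera adjusted p = 3.48e-08; adjusted p = 0.443 with an estimated correlation). Only 0, 2, 0 and 3 rose without Bil_2D replicates 1 and 2 and Hep_3D replicates 1 and 2. Insig1 and Nsdhl rose by log2 fold changes of 1.20 and 1.11 and Srebf2 fell by 0.97, and each lost its call in 3 of the 4 leave-outs. For Insig1 these were without Bil_2D replicate 1 (adjusted p = 0.0558), Hep_3D replicate 1 (0.0671) and Hep_3D replicate 2 (0.052). For Nsdhl they were without Bil_2D replicate 1 (0.132), Bil_2D replicate 2 (0.0772) and Hep_3D replicate 1 (0.0834), and for Srebf2 without Bil_2D replicate 1 (0.126), Bil_2D replicate 2 (0.0941) and Hep_3D replicate 2 (0.0624). On the median-of-ratios scale Srebf2 stood at -0.16 (adjusted p = 0.639).

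In fatty acid and triglyceride synthesis, 5 of 19 rose and 3 fell, the same adjusted over the list alone, and 9 rose and 1 fell on the median-of-ratios scale (camera adjusted p = 5.8e-05; adjusted p = 0.242 with an estimated correlation). Without Bil_2D replicate 1, Bil_2D replicate 2 or Hep_3D replicate 2, 3 rose and 1 fell. Scd1, the stearoyl-CoA desaturase, rose from 61.9 ± 14.1 to 518 ± 23.7 TPM and Dgat2, which makes triglyceride, from 22.9 ± 6.91 to 151 ± 4.5 TPM (SD, n = 2). Me1, malic enzyme, fell from 295 ± 34 to 58 ± 11.3 TPM. Elovl6 fell by 0.77 on the TPM scale and stood at 0.01 on the median-of-ratios scale (adjusted p = 0.962 there). On the TPM scale its adjusted p was 0.0548 to 0.101 as each of the 4 libraries was left out.

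YAP/TAZ targets, transcripts driven by the Hippo pathway's effectors, fell together: 18 of 20 were lower and 0 higher, 0 and 19 adjusted over the list alone and 0 and 13 on the median-of-ratios scale (camera adjusted p = 0.0017; adjusted p = 0.242 with an estimated correlation). Without Hep_3D replicate 2, 1 target rose. Cyr61 fell from 541 ± 236 to 14.3 ± 7.53 TPM and Tgfb2 from 24.5 ± 12.2 to 0.928 ± 0.295 TPM (SD, n = 2). Of 17 basement membrane and epithelial integrin genes, 14 fell and 0 rose, or 16 and 0 adjusted over the list alone and 9 and 0 on the median-of-ratios scale (camera adjusted p = 0.00397; adjusted p = 0.242 with an estimated correlation). Col4a1, a type IV collagen chain, fell from 163 ± 0.381 to 15.7 ± 2.14 TPM and Itga2 from 20.6 ± 10.7 to 0.387 ± 0.0053 TPM (SD, n = 2). Of 15 Notch pathway genes, 1 rose and 10 fell, the same adjusted over the list alone, and 4 fell on the median-of-ratios scale; 6 fell as each of the 4 libraries was left out. The list did not pass on the TPM scale (camera adjusted p = 0.31) and passed on the median-of-ratios scale (adjusted p = 0.0455). With an estimated correlation, on the TPM scale, its adjusted p was 0.511. Lfng, a Notch glycosyltransferase, fell from 29.7 ± 7.87 to 0.605 ± 0.0717 TPM, the target gene Hes1 fell from 139 ± 32 to 20 ± 1.6 TPM, and the ligand gene Dll1 rose from 0.624 ± 0.553 to 6.88 ± 2.47 TPM (SD, n = 2). The adjusted p of Dll1 was 0.0552 without Bil_2D replicate 2 and 0.0525 without Hep_3D replicate 2.

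Of 19 mesenchymal and TGF-beta response genes, 12 fell and 0 rose, the same adjusted over the list alone, and 5 fell on the median-of-ratios scale; 7 fell without Bil_2D replicate 2, Hep_3D replicate 1 or Hep_3D replicate 2. With the replicate block 1 rose. The camera test did not pass on the TPM scale (adjusted p = 0.31) and passed on the median-of-ratios scale (adjusted p = 0.00319), after quantile normalization (0.00947) and with the 50 most abundant genes left out (0.0224). With an estimated correlation, on the TPM scale, it was 0.721. Vim, the intermediate filament vimentin, fell from 927 ± 4.47 to 63 ± 25.6 TPM (SD, n = 2). Of 21 epithelial junction and keratin genes, 3 rose and 10 fell, the same adjusted over the list alone, with 4 and 4 on the median-of-ratios scale and 6 lower without Hep_3D replicate 2. Their median and mean log2 fold changes were -0.68 and -0.55, while camera leaned upward without passing (adjusted p = 0.394). The claudin gene Cldn1 and the desmosomal Dsc2 rose (log2 fold changes 3.11 and 2.22), and Krt20 and Jup, which encodes plakoglobin, fell (-3.94 and -2.15).

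Cell cycle transcripts were lower in the hepatocyte cultures: 29 of 30 fell and 0 rose, the same adjusted over the list alone, and 19 fell on the median-of-ratios scale (camera adjusted p = 0.000291; adjusted p = 0.623 with an estimated correlation). Without Bil_2D replicate 1 the number that fell was 9 and without Bil_2D replicate 2 it was 7. Ccnd1 (cyclin D1) fell from 729 ± 119 to 31.7 ± 1.55 TPM and Ccnb2 (cyclin B2) from 98 ± 10.9 to 5.05 ± 3.21 TPM (SD, n = 2). The list median was -2.23 in clone 15C7 and -3.67 in clone 19H5, a difference that was not tested. Ccne1 (cyclin E1) was the member that did not pass, and was named after its value was seen (adjusted p = 0.116). Of 20 p53 target and senescence genes, 17 fell and 0 rose, the same adjusted over the list alone, with 6 on the median-of-ratios scale 9 without Bil_2D replicate 1 and 9 without Bil_2D replicate 2 (camera adjusted p = 0.0143; adjusted p = 0.506 with an estimated correlation). Plk2 fell from 122 ± 9.85 to 8.92 ± 0.253 TPM and Gdf15, a stress-induced cytokine gene, from 181 ± 82 to 21.6 ± 4.54 TPM (SD, n = 2).

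The fetal liver and progenitor list went both ways, with 3 of 13 higher and 7 lower, the same adjusted over the list alone, 3 and 4 on the median-of-ratios scale and 4 lower without Bil_2D replicate 2. Its median log2 fold change was -1.53, its mean was 0.41 and camera leaned upward without passing (adjusted p = 0.441), and downward on the median-of-ratios scale (0.309). H19, the imprinted RNA gene neighbouring Igf2 (chromosome 7, 142575529 to 142578143), rose from 0.963 ± 0.127 to 1484 ± 1286 TPM and Igf2 from 0.568 ± 0.278 to 1752 ± 1590 TPM (SD, n = 2). Afp, alpha-fetoprotein, rose from 3.34 ± 2.39 to 77.5 ± 66.3 TPM (log2 fold change 3.98, adjusted p = 0.017 in limma), with adjusted p of 0.056 and 0.0798 without Bil_2D replicates 1 and 2. Peg3, a paternally expressed imprinted gene, fell from 400 ± 146 to 64.1 ± 13.7 TPM and the chromatin protein gene Hmga2 from 41.7 ± 10.2 to 6.57 ± 0.208 TPM.

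Immediate early and unfolded protein response genes went both ways: 7 of 21 rose and 8 fell, the same adjusted over the list alone, and 9 and 4 on the median-of-ratios scale. Camera gave an upward call (adjusted p = 0.00437; adjusted p = 0.242 with an estimated correlation) although the median and mean log2 fold changes were -0.37 and -0.28, and the call was lost on the median-of-ratios scale (adjusted p = 0.0802) and after quantile normalization (0.0647). Without Bil_2D replicates 1 and 2 the number that rose was 4 and 3, and without Bil_2D replicate 1 and Hep_3D replicate 2 the number that fell was 5 and 5. The chaperone gene Dnajb9, induced in the unfolded protein response, rose from 25.1 ± 2.55 to 82.3 ± 15 TPM (SD, n = 2), and the heat shock gene Hspa1b from 18 ± 0.864 to 60 ± 27.5 TPM. The adjusted p of Hspa1b was 0.0875 and 0.0924 without Bil_2D replicates 1 and 2. The AP-1 subunit gene Fosl1 and the phosphatase gene Dusp1 fell, with log2 fold changes of -3.74 and -3.18.

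Chemokine and acute phase genes also moved apart, with 5 of 19 higher and 8 lower, 5 and 9 adjusted over the list alone, and 5 and 3 on the median-of-ratios scale. Without Bil_2D replicate 1, Bil_2D replicate 2 and Hep_3D replicate 1, 4, 4 and 5 fell. The median log2 fold change was -1.91 and the mean 0.24. The upward camera call (adjusted p = 0.0218; adjusted p = 0.506 with an estimated correlation) was lost without Hep_3D replicate 2 (0.184), without the filter (0.132) and after quantile normalization (0.823). It turned downward on the median-of-ratios scale (0.912) and with the 50 most abundant genes left out (0.125), passing in neither. Leaving out those 50 genes removed members of the list itself, with 15 tested in place of 19. That run therefore did not test the same list. The acute phase genes Saa2 and Orm2 rose by log2 fold changes of 9.98 and 9.18, Orm2 from 12.5 ± 6.7 to 7928 ± 4293 TPM (SD, n = 2). The monocyte chemokine gene Ccl2 fell from 3024 ± 436 to 230 ± 241 TPM (adjusted p = 0.0213 in limma). On the median-of-ratios scale the log2 fold change of Ccl2 was -3.455 and did not pass (adjusted p = 0.0743 in limma). The fold change was -4.42 and -4.12 without Bil_2D replicates 1 and 2, and the call was lost in both. Ccl7 fell from 398 ± 302 to 28.6 ± 33.4 TPM (adjusted p = 0.0423). It lost its call with the replicate block (0.0647), on the median-of-ratios scale (0.124) and without Bil_2D replicate 1 (0.17), Bil_2D replicate 2 (0.0852) or Hep_3D replicate 1 (0.0952).

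Interferon and hypoxia genes formed 2 lists. Of 21 interferon response genes, 0 rose and 8 fell, or 0 and 7 adjusted over the list alone, and 0 passed either way on the median-of-ratios scale. The number lower was 1, 0, 4 and 0 without Bil_2D replicates 1 and 2 and Hep_3D replicates 1 and 2. The median and mean were -0.68 and -0.67 while camera leaned upward without passing (adjusted p = 0.721), and downward on the median-of-ratios scale (0.912). Gbp2 and Ddx58 fell by 1.60 and 1.36 on the log2 scale, and neither passed on the median-of-ratios scale (adjusted p = 0.0845 and 0.131). Gbp2 lost its call without Bil_2D replicate 2 (adjusted p = 0.066), Hep_3D replicate 1 (0.0514) and Hep_3D replicate 2 (0.0778). Ddx58 lost its call without Bil_2D replicate 1 (0.0785), Bil_2D replicate 2 (0.0517) and Hep_3D replicate 2 (0.0747). Of 17 hypoxia response genes, 0 rose and 5 fell, or 0 and 3 adjusted over the list alone, and 1 rose and 0 fell on the median-of-ratios scale. The number lower was 2, 0, 2 and 2 as the libraries were left out in the same order, and 1 rose without Bil_2D replicate 2. With the replicate block 2 hypoxia genes rose and 8 fell, and 0 interferon genes rose and 10 fell. Camera leaned upward (adjusted p = 0.443, and 0.049 without Bil_2D replicate 2), against a median of -0.51 and a mean of -0.46. Adm and P4ha1 fell by 1.18 and 1.15, and did not pass on the median-of-ratios scale (adjusted p = 0.0877 and 0.426). Adm lost its call without Bil_2D replicate 1 (0.0706), Bil_2D replicate 2 (0.0542) and Hep_3D replicate 2 (0.0561). P4ha1 lost its call without Bil_2D replicate 1 (0.078), Bil_2D replicate 2 (0.137) and Hep_3D replicate 1 (0.0981).

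Genes that mark zones of the liver lobule formed 2 lists. Of 13 periportal genes, 9 rose and 1 fell, or 9 and 2 adjusted over the list alone (camera adjusted p = 3.4e-12; adjusted p = 0.151 with an estimated correlation). The number that fell was 2 without Hep_3D replicate 1, 0 without Hep_3D replicate 2 and 2 with the replicate block. Hsd17b13, a lipid droplet enzyme, rose from 3.29 ± 0.593 to 1015 ± 261 TPM and Arg1 rose as above, while Cdh1 (E-cadherin) fell from 183 ± 60.7 to 49.8 ± 3.15 TPM (SD, n = 2). The adjusted p of Cdh1 was 0.0535 on the median-of-ratios scale and 0.0516 without Hep_3D replicate 2. Of 12 pericentral genes, 2 rose and 8 fell, the same adjusted over the list alone, 2 and 2 on the median-of-ratios scale, and 4 fell as each of the 4 libraries was left out. Median and mean were -0.97 and -0.56 while camera leaned upward without passing (adjusted p = 0.511), and downward on the median-of-ratios scale (0.493). Cyp27a1 rose from 9.05 ± 3.22 to 51.6 ± 9.28 TPM and Cyp1a2 from 0.288 ± 0.152 to 5.7 ± 4.23 TPM (SD, n = 2). The adjusted p of Cyp1a2 was 0.0911 and 0.103 without Bil_2D replicates 1 and 2. Axin2, a Wnt target, fell from 7.69 ± 1.76 to 0.935 ± 0.333 TPM. Lect2 fell from 92.8 ± 64.3 to 8.3 ± 4.94 TPM. For Lect2 the adjusted p was 0.0748 on the median-of-ratios scale, 0.0619 without Bil_2D replicate 2 and 0.0773 without Hep_3D replicate 1.

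**Figure D3:**
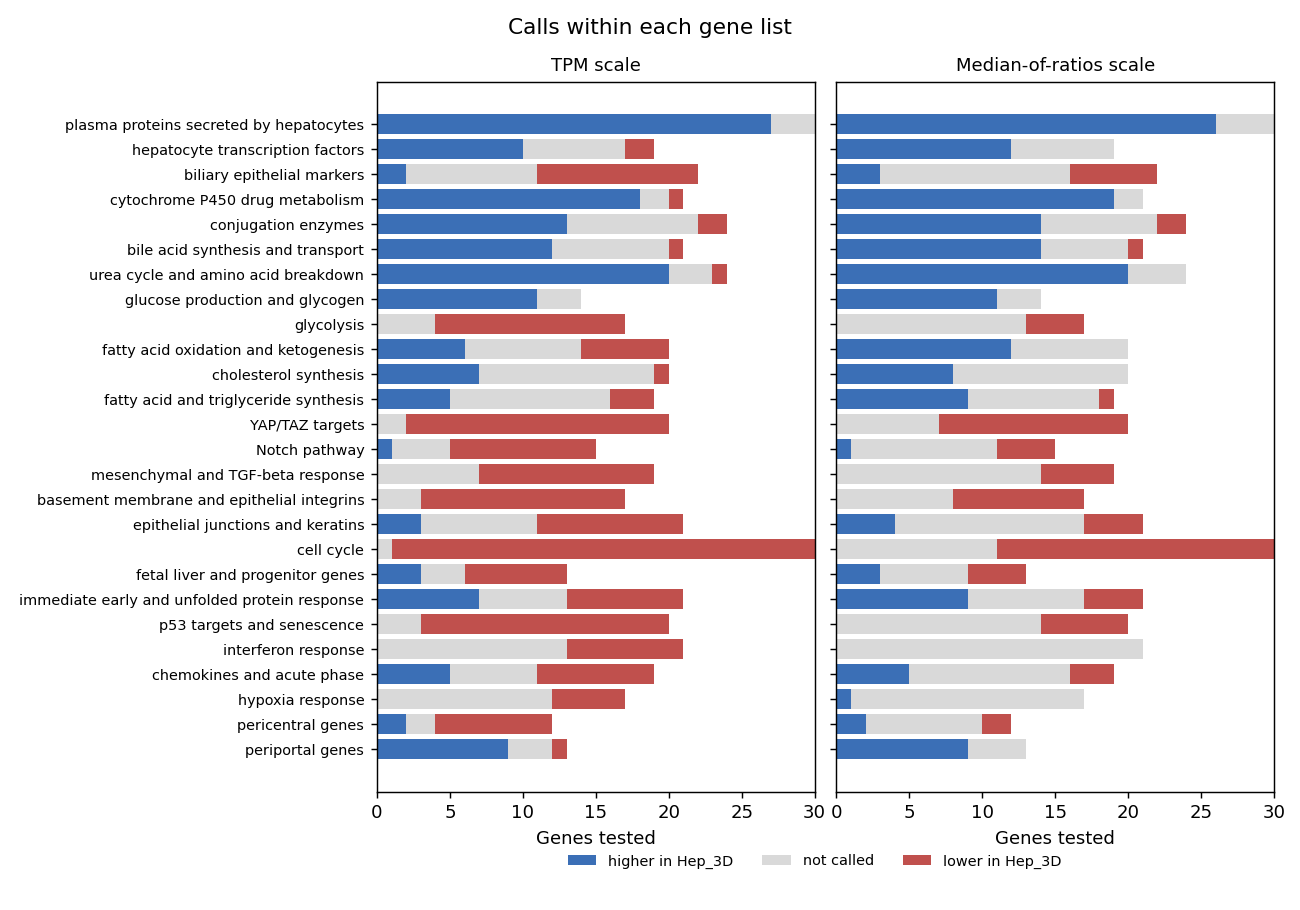
Number of genes tested in each of 26 lists, split into those higher in Hep_3D (blue), not called (grey) and lower in Hep_3D (red), on the TPM scale (left) and the median-of-ratios scale (right). Plasma protein genes are higher for 27 of 30 and 26 of 30 members on the 2 scales, and cell cycle genes lower for 29 and 19 of 30.

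Markers of other liver cell types were mostly under the filter. Of the fibroblast and stellate cell list 4 genes were tested, 0 higher and 1 lower, the same adjusted over the list alone: Ecm1 fell from 146 ± 9.27 to 27.1 ± 12.4 TPM (SD, n = 2), with adjusted p of 0.00818 in limma, and 0.0506 and 0.0525 without Bil_2D replicates 1 and 2. Of the macrophage and leukocyte list 3 were tested, 0 higher and 1 lower, the same adjusted over the list alone: Cd68 fell from 8.08 ± 5.06 to 1.21 ± 0.754 TPM (adjusted p = 0.0322, and 0.141 on the median-of-ratios scale). It lost its call without Bil_2D replicate 2 (0.0924), Hep_3D replicate 1 (0.132) and Hep_3D replicate 2 (0.077). Without Hep_3D replicate 2, 1 gene rose in each of these 2 lists, and with the replicate block 1 rose in the fibroblast and stellate cell list. Dcn, of the fibroblast and stellate cell list, was named after its values were seen. It had 2.38 and 0 TPM in Bil_2D replicates 1 and 2, and 178 and 2.785 TPM in Hep_3D replicates 1 and 2. Its log2 fold change of 3.82 did not pass (adjusted p = 0.163 in limma). The endothelial list had 1 gene tested, Egfl7, at 11.3 ± 2.5 and 8.94 ± 2.81 TPM (adjusted p = 0.376). The red blood cell list had 2, Hba-a1 at 4.44 ± 1.25 and 2.47 ± 0.0401 TPM and Hbb-b1 at 1.23 ± 0.803 and 1.6 ± 0.502 TPM (adjusted p = 0.0869 and 0.556), with 0 calls in either list, also adjusted over the list alone.

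The second comparison asked which transcripts differed between the clones, with cell state as a term. Clone 19H5 had lower levels than clone 15C7 of Hamp, the gene of the iron hormone hepcidin (chromosome 7, 30942368 to 30944032), in both states: 1390 and 13.9 TPM in Bil_2D of clones 15C7 and 19H5, and 114 and 0.448 TPM in Hep_3D (log2 difference -6.43, adjusted p = 0.085 in limma). The Y-linked genes Ddx3y and Eif2s3y stood at 23 and 43.7 TPM in Bil_2D and 23.2 and 25.3 TPM in Hep_3D of clone 15C7, and in clone 19H5 Ddx3y stood at 0.0505 and 0.0602 TPM and Eif2s3y at 0.0515 and 0 TPM. Aebp1 and Crip1 had log2 differences of -2.95 and -2.88. Genes with higher values in clone 19H5 included Praf2 (log2 difference 4.76), BC002163 (1.23 and 0 TPM in Bil_2D and Hep_3D of clone 15C7, 118 and 109 in clone 19H5), Camk2b, Snora44 (listed at 0 in both libraries of clone 15C7) and Nr1h4, which encodes the bile acid receptor, at 36.3 and 107 TPM in Bil_2D of clones 15C7 and 19H5 and 16.5 and 48 TPM in Hep_3D. None of these passed: 0 of 12336 genes did at an adjusted p under 0.05 with limma. Of these genes, 1599 (13%) had an unadjusted p under 0.05 and the fit had 1 residual degree of freedom. With the 50 most abundant genes left out, 1 gene passed, Hamp (adjusted p = 0.0297, with a range of 0.0297 to 1 for the smallest adjusted p over the alternatives). The median absolute log2 difference was 0.198 between clones on the TPM scale and 0.445 between states on the median-of-ratios scale. On those scales 124 and 996 genes differed by at least 2, so the clone and state values are not on the same scale.

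On the median-of-ratios scale 10153 of the 12336 genes (82.3%) changed in the same direction in both clones, where independent directions would give 49.9%. On the TPM scale, which holds the shared shift, these values were 11209 genes (90.9%) and 70.5%. On that scale, across genes, which are not independent replicates, Pearson's r of the 2 clones' changes was 0.885 and Spearman's rho 0.827.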

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

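The checks of abundant genes, of carry-over and of mislabelling below were chosen after the result was seen. Single libraries gave changes of opposite sign in the 2 clones for 8 results, and in each case the difference between clones was not tested, since a clone has 1 library per state. Hbb-b1 changed by 0.83 (log2, Hep_3D minus Bil_2D) in clone 15C7 and by -0.31 in clone 19H5. The median log2 change of the cholesterol synthesis list was 0.65 in clone 15C7 and -0.21 in clone 19H5, that of fatty acid and triglyceride synthesis 0.38 and -0.14, and that of the immediate early and unfolded protein response list 0.0501 and -0.16. For the 4 fibroblast and stellate cell markers tested, the median was -0.12 and 0.10. That of the 3 macrophage and leukocyte markers tested was 0.18 and -0.40. The 2 red blood cell genes tested include Hbb-b1, so these 2 results are not separate, and their median was 0.23 and -0.60. For the list of the endoplasmic reticulum's secretory machinery, chosen after the data were seen, the median was 0.0813 and -0.00821. On the median-of-ratios scale all of these but the red blood cell genes had the same sign in both clones, with 1.47 and 0.59 for cholesterol synthesis and 0.75 and -0.04 for red blood cell genes.

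On the TPM scale 6402 of the 7241 called genes were lower in the hepatocyte cultures. With the 50 most abundant genes left out and the rest rescaled, the median log2 change of all genes went from -0.73 to -0.25, 34.4% of its size. These genes were ranked in the same libraries, and their larger share of the TPM in Hep_3D lowers all others by construction. The run therefore measures how much of the shift goes with that share and is not a test of a cause. Gene length does not account for the shift, since 3 sets of 4060 genes with the shortest, middle and longest transcripts had medians of -0.71, -0.76 and -0.73. A difference in total RNA per cell was not tested and stays open, as does the share of the shift that remains.

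In the biliary library of clone 15C7, 10 of the 30 plasma protein genes, picked after the values were seen among those with at least 100 TPM in 15C7 hepatocytes, stood at least 3 times above that of clone 19H5, for example Ttr at 1165 and 125 TPM and Alb at 140 and 18.4 TPM. Other members were closer or went the other way, with 22 of the list higher and 8 lower in 15C7, for example Kng1 at 5.79 and 7.98 TPM. Carry-over of hepatocytes or their RNA in that culture would bring every plasma protein transcript at about the same share of its level in 15C7 hepatocytes, and the lowest share among the 10 genes was that of Alb, 0.932%. Over the whole list, 33.3% of the genes stood below 0.311%, which is 1/3 of that share, among them Ahsg at 0.0983% and Serpina3k at 0.0129%, which argues against such carry-over as the whole source. Carried-over cells with another profile than the 3D hepatocytes were not tested and stay open, as does a difference between the clones' biliary cells in how much hepatocyte expression they hold.

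The 4 Y-linked genes tested, Ddx3y, Eif2s3y, Kdm5d and Uty, stood at 4.56 TPM or more in both 15C7 libraries and at 0.0602 TPM or less in both 19H5 libraries; Kdm5d and Uty were named after their values were seen. A clone from a female would be expected to express Xist, but its highest level in the 19H5 libraries was 0.0293 TPM. Neither 15C7 library stood above that level, so the data hold no sample in which Xist is known to be detectable. A female origin of clone 19H5 is therefore not excluded. A single library swapped between the clones would break the split by clone, and 0 of the Y-linked genes did so. This is read from the split itself and is not a separate test. Loss of the Y chromosome or of its expression in clone 19H5 stays open as a hypothesis, and a donor difference was not tested.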

How the results depend on the processing

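The combined runs of median-of-ratios scaling with the replicate block, with a minimum fold change and with libraries left out were chosen after seeing the data; all other alternatives were fixed before. Of 102 named genes, 87 could be tested under every alternative, since some filters and scalings leave genes out, and 57 of these kept direction and side of the threshold throughout. Under the 3 scalings 95 could be tested and 75 kept both. With clone as a replicate block (paired by clone) 8150 genes were called, 7145 of them shared in direction with the 7241 called without it; Ccl7 (adjusted p = 0.0647) and Spp1 (0.0611) lost their calls and Sox9 (0.0302) gained one, and the block changed no other call of a named gene or list. Median-of-ratios scaling gave 2642 genes (3193 with the block, 1972 at a log2 fold change of 1 or more), quantile normalization 3100, the 50 most abundant genes left out 3350, and a minimum log2 fold change of 1 on the TPM scale 4564. Leaving out single libraries gave 2627 to 4537 genes, and 188 to 818 on the median-of-ratios scale; the smaller number of libraries lowers the count. The share higher in Hep_3D, 6.8%, was 4.05% without the filter, 11.9% by median-of-ratios, 11% after quantile normalization and 3.52% to 4.82% with single libraries left out. The share lower, 51.9%, was 29.4% without the filter, 9.54% by median-of-ratios, 14.1% after quantile normalization, 17.4% with the 50 most abundant genes left out, 31.3% at a log2 fold change of 1 and 17.8% to 32% with single libraries left out. Without the filter 18606 genes were tested. For the clones, leaving out the 50 most abundant genes gave 1 gene, and leaving out a library leaves no residual degrees of freedom and so no test. Of 18 list calls, 0 held with an estimated correlation, a test with little power at 2 residual degrees of freedom.

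Named genes that lost their call without a library numbered 21 (Bil_2D replicate 1), 26 (Bil_2D replicate 2), 15 (Hep_3D replicate 1) and 14 (Hep_3D replicate 2). Changes of sign were Cpt1a (0.0501) and Elovl6 (0.0132) by median-of-ratios, Egfl7 (0.42 by median-of-ratios, 0.34 after quantile normalization, 0.18 with the 50 most abundant genes left out), and, without Bil_2D replicate 1, Epcam (0.0176) and Hbb-b1 (-0.12). With single libraries left out Epcam ran from -0.966 to 0.0176 and Hbb-b1 from -0.12 to 0.637. List tests that changed sign had adjusted p of 0.173 (median-of-ratios), 0.172 (quantile), 0.169 (50 genes left out) and 0.972 (without Hep_3D replicate 2; lowest without a library 0.514) for biliary markers, 0.309, 0.555 and 0.612 under the same 3 scalings for fetal genes, and 0.912 (median-of-ratios) and 0.125 (50 genes left out) for chemokines and acute phase, which ended that list's call. Others were interferon (0.609 without the filter, 0.912 by median-of-ratios, 0.855 without Bil_2D replicate 1, 0.737 without Hep_3D replicate 1, lowest without a library 0.312), hypoxia (0.92 without the filter, 0.736 without Bil_2D replicate 1, lowest 0.049 without Bil_2D replicate 2) and pericentral genes (0.793 with a filter of 5 TPM, 0.493, 0.665 and 0.775 under the 3 scalings). With the 50 most abundant genes left out, 15 of the 19 chemokine and acute phase genes were tested, so the list was not the same. Apart from the numbers of libraries and genes tested, the cause was not tested. Depth is unknown, so the precision of low values cannot be given.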

Other observations

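The 8 gene lists given first and the test on shuffled chromosomes were chosen after the data were seen, as were the genes named from these lists and the test of imprinted genes. Complement genes were higher in the hepatocyte cultures: 14 of 19 rose and 1 fell, 15 and 0 on the median-of-ratios scale (camera adjusted p = 6.97e-20; adjusted p = 0.311 with an estimated correlation). Serping1, the C1 inhibitor gene, had 1.08 and 0.471 TPM in Bil_2D replicates 1 and 2 and 712 and 165 in Hep_3D, C9 had 3.42 and 0.537 against 388 and 410, and Masp1 fell (log2 fold change -2.18; adjusted p = 0.0987 on the median-of-ratios scale). Genes of the endoplasmic reticulum's secretory machinery had 5 of 39 higher and 7 lower on the TPM scale and 24 and 0 on the median-of-ratios scale, with a median of 0.08 and 0.89 on those scales (camera adjusted p = 7.34e-07; adjusted p = 0.432 with an estimated correlation). Dnajc3 and Srpr rose on both scales. These genes are a hypothesis for follow-up beside the plasma protein genes.

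Cytosolic ribosomal protein genes fell on the TPM scale, 79 of 81, with a median of -1 (camera adjusted p = 4.88e-06; adjusted p = 0.663 with an estimated correlation), and on the median-of-ratios scale 0 genes passed in either direction. The list still passed downward there (adjusted p = 0.00283), with a median of -0.18. The nuclear-encoded respiratory chain had 1 of 82 higher and 41 lower on the TPM scale and 8 and 0 on the median-of-ratios scale, and its test leaned downward without passing (adjusted p = 0.333) and passed upward on the median-of-ratios scale (adjusted p = 0.000173). With an estimated correlation, on the TPM scale, its adjusted p was 0.902. The hypothesis that imprinted genes other than Igf2 and H19 were higher was left undecided: 0 of 18 rose and 10 fell, or 2 and 3 on the median-of-ratios scale, and the test leaned upward with adjusted p = 0.772 and downward on the median-of-ratios scale (0.242). The medians were -0.87 and -0.235 on the 2 scales. Of 29 squamous genes beside Sprr1a, 27 matched and only 6 were tested. Krt5, Krt14 and Trp63 were under the filter, at 0.191 TPM or less in every library. Of the 6 tested, 4 were lower, or 3 on the median-of-ratios scale, with Sprr1b at 20.4 and 23.5 TPM in Bil_2D and 0 and 0.118 in Hep_3D (adjusted p = 0.13, and 0.00209 on the median-of-ratios scale). With an estimated correlation, on the TPM scale, it was 0.432. The small nucleolar RNA list, expected higher, had 1 of 76 higher and 23 lower, or 2 and 10 on the median-of-ratios scale. Its medians were -1.27 and -0.60 on the 2 scales. Camera leaned upward against other genes (adjusted p = 0.772) and passed downward on the median-of-ratios scale (0.0346). For the values as listed, this argues against the expectation. Many members were listed at 0 in a library, and Snord53 and Snord73a had the same values in every library. The levels of these RNAs are therefore uncertain, and the members are not all separate measurements. With an estimated correlation, on the TPM scale, the list's adjusted p was 0.902. Gastrointestinal epithelium genes, expected lower, passed upward on the TPM scale (adjusted p = 0.00247; adjusted p = 0.311 with an estimated correlation) and not on the median-of-ratios scale (0.242). On the TPM scale 2 of 10 were higher and 1 lower, and 1 and 0 on the median-of-ratios scale, with a median of 0.06 and a mean of 1.25. Cdx2, an intestinal transcription factor, fell from 15.7 and 11.3 TPM in Bil_2D replicates 1 and 2 to 0.117 and 3.5 in Hep_3D (adjusted p = 0.0353, and 0.142 on the median-of-ratios scale). Muc13 (adjusted p = 0.00803, and 0.0139 on the median-of-ratios scale) and Reg3g (0.0358 and 0.0535) rose on the TPM scale. Reg3g had 6.02 and 0 TPM in Bil_2D replicates 1 and 2, and 993 and 50.7 TPM in Hep_3D replicates 1 and 2. Reg3b, with 8.63 and 0 TPM against 1763 and 45.2 TPM, did not pass (adjusted p = 0.0555 in limma). Tff3 did not pass (adjusted p = 0.147) and was listed at 0 in both Bil_2D libraries and stood at 1.89 and 810 TPM in Hep_3D replicates 1 and 2.

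The difference between clones, 19H5 minus 15C7, varied by chromosome in the same way in both states, which share no libraries. Over 11761 genes on 19 autosomes, 7 autosomes had a median of at least 0.1 in size with the same sign in both states, and the highest count in 1000 shuffles of genes over chromosomes was 0, which argues against clone-different genes being spread over the chromosomes at random. The medians in biliary and hepatocyte cultures were -0.20 and -0.17 for chromosome 13, -0.18 and -0.22 for chromosome 15 and 0.16 and 0.22 for chromosome 19. Across the autosomes Pearson's r was 0.91 and Spearman's rho 0.9, each with a permutation p of 1e-05, the smallest that 100000 permutations can give, and r was 0.899 without chromosomes 13 and 15. A gain or loss of a whole chromosome in a clone, or in part of its cells, cannot be told apart from other causes here: 0 autosomes reached a median of 0.3 in both states, the largest was 0.277, and chromosomes 13, 15, 18 and 19 lay more than 0.2 from 0 in at least 1 state.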
